A study of Mus musculus with 2 samples.

How the data were processed

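Nuclei of the inguinal mammary fat pad, taken from 8 lactating mice on day 11 after birth of the pups with the lymph nodes removed, were sequenced as 1 pooled 10x Genomics library, with a second library of hashtags (DNA-barcoded tags that mark the animal of each nucleus). The study's labels name 4 animals with a floxed oxytocin receptor gene (Oxtr) and 4 animals with Oxtr deleted in adipocytes. The deposited hashtag reference names 4 hashtags WT, 4 hashtags Oxtr-KO and 2 as unknown samples. The fixed design asked for a genotype name in words that match the labels, and WT does not match them. WT was still taken as the floxed group, because that is the only other genotype the labels give. This departs from the design as written, and every comparison of genotypes rests on it. Animals were 8 weeks old at breeding, and the labels list 7 litters of 5 pups and 1 litter of 3 without tying a litter to an animal. The labels give these litters as the batch.

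The authors deposited raw counts of unique molecular identifiers (UMIs) per gene and nucleus, which are whole numbers and not normalized. Per the submitters' processing notes, fastp and Cell Ranger 7.2.0 were used with the build GRCm39. The roles of fastp and the annotation release are not given in the sources used here. The second deposited table gives the read count behind each hashtag UMI, so its lines were counted to give hashtag UMIs per barcode, and 61.4% of hashtag UMIs rested on 1 read. How hashtag reads were assigned is not given in the sources used here. The reference genome at hand has the build GRCm38, so no coordinates are printed, and gene symbols and identifiers are those of the deposited gene list. A symbol that occurred more than once, as 38 did, was kept as separate genes. Deposited text columns (barcodes, symbols and the names of the hashtags) served only to join the tables.

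The matrix held 21805 barcodes, 33943 genes and 107910356 UMIs, with a median of 4212 UMIs and 1794 genes per barcode and no barcode under 500 UMIs. Barcodes with at least 500 UMIs, at least 300 genes and under 5% mitochondrial UMIs were kept, which left 20854 and removed 951. Animals were called with HTODemux of Seurat 5.3.0 on centred log ratios across barcodes with a positive quantile of 0.99, using 9 of the 10 hashtags. The hashtag Unknown_sample1, with 12088 UMIs, was left out of the calling after the hashtag counts had been seen. Of the kept barcodes, 12998 carried the hashtag of 1 named animal, 265 that of Unknown_sample2, 5647 no called hashtag, and 1944 more than 1 hashtag. The last group was removed as doublets. Scrublet's automatic threshold marked 1 of 20854 barcodes and so did not work. An added alternative removed the barcodes with the highest 5% of Scrublet scores (1131 with ties). It marked 17.4% of the hashtag doublets and 4.38% of the barcodes with 1 animal. Doublets of nuclei from the same animal are not seen by hashtags.

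The 18910 barcodes that were not hashtag doublets were clustered with scanpy 1.11.5 under Python 3.11.15 (counts scaled to 10000 per nucleus, log transform, 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.5). Clusters took a cell type name only from marker lists fixed before the data were examined, as were the gene lists, the main tests, the alternatives called planned and the rule for the genes named. A named cluster stands for nuclei that are like that type by at least 3 markers. Names were left off after the clusters were seen where the leading genes matched no fixed list. The cluster led by Klra2, Fyb and Lair1 had 5 macrophage and 3 dendritic markers but none among its 10 leading genes, so it carries the name of its first gene. The low-depth cluster (median 1499 UMIs) had 6 secretory luminal markers but is led by mitochondrial genes, and the cluster led by Nrg3 and Kcnip4 had at most 2 markers of a list. These 2 stay outside the comparisons, as does a hormone-sensing luminal cluster of 59 nuclei, with 6 markers of its own but more of another class, 1 against 0, among its 10 leading genes. The dendritic cluster of 21 nuclei kept its name with 4 markers, though none was among its 10 leading genes.

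Counts were summed per animal and cell type, for types with at least 10 nuclei in at least 3 animals of each genotype. Alternative settings were fitted where at least 2 animals of each genotype were left. The sums were tested with the quasi-likelihood test of edgeR 4.0.16 (TMM scaling, filterByExpr, genotype as the only term, R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05. Expression of tested genes is given as TMM-scaled CPM (UMIs scaled to a common library total), and of Oxtr, Got1 and Plpp4 across cell types as plain CPM of the summed UMIs. DESeq2 1.42.0 was run as an alternative. The 18 gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry, where at least 5 members were measured. They hold lipolysis, fatty acid synthesis, triglyceride synthesis, fatty acid uptake, milk proteins, milk fat secretion, cholesterol synthesis, fatty acid oxidation, the respiratory chain, insulin and glucose metabolism, adipocyte identity, extracellular matrix, inflammatory genes, immediate early genes, the circadian clock, oxytocin receptor signalling, involution and the cell cycle. Values per animal were compared with two-sided exact permutation tests over the 70 assignments of 4 animals against 4, which cannot give a p below 0.0286. The first principal component used the 500 most variable genes in log2 CPM with a prior count of 2, without TMM scaling except where TMM is named. Summed adipocyte UMIs ran from 169108 to 360073 per animal and summed secretory luminal UMIs from 4253220 to 9093320. Intervals on counts are exact Poisson intervals at 95% and cover counting error only.

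The genes named were chosen by a fixed rule. It takes Oxtr, then up to 10 rising and 10 falling genes past the threshold with descriptive symbols per main comparison, then per list up to 4 members past the threshold or else the 2 members with the smallest p. In other cell types it takes up to 5 genes past the threshold. Genes named outside this rule are marked as such. Not every gene that the rule takes for a list is printed. Recovery was tried on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold per cell type. That many changes ease the adjusted threshold, and genes were drawn independently of each other. With few real changes the recovery may thus be lower. In counts simulated from the adipocyte sums over 3631 genes, edgeR recovered 49% of genes changed 2-fold and 85% of those changed 4-fold, with 9 false among 143 calls. In secretory luminal sums over 12670 genes it recovered 74% and 93%, with 12 false among 179 calls. In myoepithelial sums over 6284 genes it recovered 76% and 90%, with 11 false among 177 calls.

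The alternatives were DESeq2's size factors and test, no count filter, leaving out each animal, the replicate number as a block, leaving out 219 free-RNA genes, a minimum of 1000 UMIs, Leiden resolution 1.0, and a ratio rule for hashtags (top hashtag with at least 10 UMIs and at least 3 times the next). Free-RNA genes had a UMI in at least 25% of the nuclei of every tested type and their highest CPM in secretory luminal nuclei. The genes of the milk protein list were added to them whatever their detection. Added after the data were seen were hashtag calling with all 10 hashtags, centred log ratios within barcodes, a background rule (top hashtag at least 3 times its own median and the next at most 0.6 of it on that scale), the removal by Scrublet score, and, for the gene lists, the block, the minimum of 1000 UMIs and an estimated correlation without WT animal 4. Nuclei with no hashtag were clustered and then left out of all comparisons between genotypes, as were those of the unknown hashtags.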

Results

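Single nuclei of the mammary fat pad were profiled in 8 lactating dams, 4 WT (Oxtr floxed) and 4 labelled as adipocyte-specific Oxtr knockouts, to ask what the adipocyte oxytocin receptor does for the gland that makes milk fat. Each animal gave 1246 to 2013 nuclei. These numbers depended on the hashtag rule: the ratio rule left 62 to 1698 nuclei per animal, and centred log ratios within barcodes gave 770 to 3321. Nuclei given to the wrong animal would blur differences between the genotypes, and how many there were was not tested. The median depth was 5185 ± 401 UMIs per nucleus in WT animals (SD, n = 4) and 4737 ± 381 in the animals labelled knockout (SD, n = 4), a difference of -447 with an exact permutation p of 0.2. Genes per nucleus (2023 ± 63.1 against 1950 ± 67.7, exact permutation p = 0.2) and nuclei per animal (1682 ± 259 against 1567 ± 295, exact permutation p = 0.6) differed by less than could be called. Median mitochondrial UMIs were 0.102 ± 0.00942% and 0.124 ± 0.00842% (SD, n = 4 each, exact permutation p = 0.0571). That p fell to 0.0286 with at least 1000 UMIs, with centred log ratios within barcodes and with the background rule. Secretory luminal cells, the milk-making cells, made up 9736 of the assigned nuclei. The others named here were 913 myoepithelial, 679 fibroblast, 370 adipocyte, 259 luminal progenitor, 195 vascular endothelial and 180 macrophage nuclei, and 215 nuclei of the cluster led by Klra2. The luminal progenitor name depends on the clustering: of the 344 nuclei clustered under it, 101 kept it at a Leiden resolution of 1.0, and 240 fell in a cluster with only 2 markers of that list. All animals shared 1 pool and 1 library. How each animal was handled before pooling is not given in the sources used here. Per the labels' protocols, only some of the samples had their nuclei washed against free RNA, without saying which.

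Oxtr (ENSMUSG00000049112.10), which encodes the oxytocin receptor, was not lower in adipocyte nuclei of the animals labelled knockout but higher in 4 of 4. WT animals 1 to 4 had 1 Oxtr UMI each there, at 4.40, 5.81, 4.65 and 5.91 CPM. Animals 1 to 4 labelled knockout had 4, 5, 5 and 4 UMIs, at 14.3, 13.9, 22.7 and 15.7 CPM. The means were 5.19 ± 0.780 and 16.6 ± 4.10 CPM (SD, n = 4 each), a difference of 11.4 CPM with an exact permutation p of 0.0286, the smallest this design can give, and 0.114 after adjustment over 8 cell types, so it did not pass. Pooled over animals, 4 UMIs (95% Poisson interval 1.09 to 10.2) stood against 18 (10.7 to 28.4). The targeted gene thus showed no fall with the label, and the animals are called "labelled knockout" for that reason. With 1 UMI in each WT animal, a fall could hardly have been seen. Pooled over WT animals, Oxtr was at 5.10 CPM in adipocyte nuclei, 3.90 in secretory luminal nuclei and 8.65 in macrophage nuclei. The missing fall thus neither shows nor excludes the deletion. A 3′ tag outside the deleted part of a gene checks nothing, and where these tags lie relative to the deletion is not given in the sources used here.

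In myoepithelial nuclei, the contractile cells in which oxytocin acts on milk ejection, Oxtr stood at 226 ± 21.6 CPM in WT animals and 180 ± 13.3 CPM in the animals labelled knockout (SD, n = 4 each, exact permutation p = 0.0286, adjusted 0.114). edgeR gave a log2 fold change of -0.35 ± 0.14 (SE) with an adjusted p of 0.548 over all genes tested. With the ratio rule for hashtags, which left 2 animals of each genotype, the difference turned to 70.5 CPM. In other types, assumed here to lack the receptor, no difference passed. Fibroblasts had 2.93 ± 2.37 and 12.2 ± 11.5 CPM (5 and 21 UMIs, exact permutation p = 0.0857), macrophages 5.83 ± 10.1 and 18.3 ± 10.8 (3 and 9 UMIs, exact permutation p = 0.171), and the cluster led by Klra2 7.32 ± 1.87 and 20.0 ± 16.3 (6 and 18 UMIs, exact permutation p = 0.257). Single animals carry much of these differences. Animal 4 labelled knockout had 12 of the 21 fibroblast UMIs, and without it the difference fell from 9.31 to 3.66 CPM. In the cluster led by Klra2, animal 2 labelled knockout had 11 of 18 UMIs and animal 3 had 0. The difference there was 12.7 CPM, 7.51 without animal 2, 19.4 without animal 3 (exact permutation p = 0.0286) and 29.6 with all 10 hashtags (exact permutation p = 0.0286). All 3 macrophage UMIs of WT animals came from WT animal 4. Whether any of these types differs from adipocytes in its Oxtr change is left open. Luminal progenitors (13.6 and 6.62 CPM, 8 and 6 UMIs, exact permutation p = 0.371) lay the other way, with WT animal 2 at 27.7 CPM and WT animal 4 at 0. So did vascular endothelial nuclei (19.1 and 5.11 CPM, exact permutation p = 0.543), but only through WT animal 1 at 63.6 CPM. Without it the difference was 0.824 CPM, without the highest Scrublet scores 2.05 and with the background rule 0.610. In secretory luminal nuclei Oxtr was at 3.91 ± 0.926 and 4.47 ± 0.801 CPM (SD, n = 4 each, exact permutation p = 0.429). An Oxtr UMI was seen in 53.2% of myoepithelial, 4.32% of adipocyte and 2.30% of secretory luminal nuclei, where the clustered nuclei of these types had median depths of 2527, 4099 and 5080 UMIs. Macrophage nuclei, assumed here to lack the receptor, had an Oxtr UMI in 6.67% at a median depth of 2196.5 UMIs, and fibroblast nuclei in 2.50%. The adipocyte share, taken over both genotypes, thus does not show whether adipocytes express Oxtr, and background is not excluded. With all 10 hashtags the adipocyte difference was 11.6 CPM with an exact permutation p of 0.4, and with the background rule 12.8 CPM with an exact permutation p of 0.0857. Without the highest Scrublet scores it was 7.19 CPM (exact permutation p = 0.0286).

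**Figure D1:**
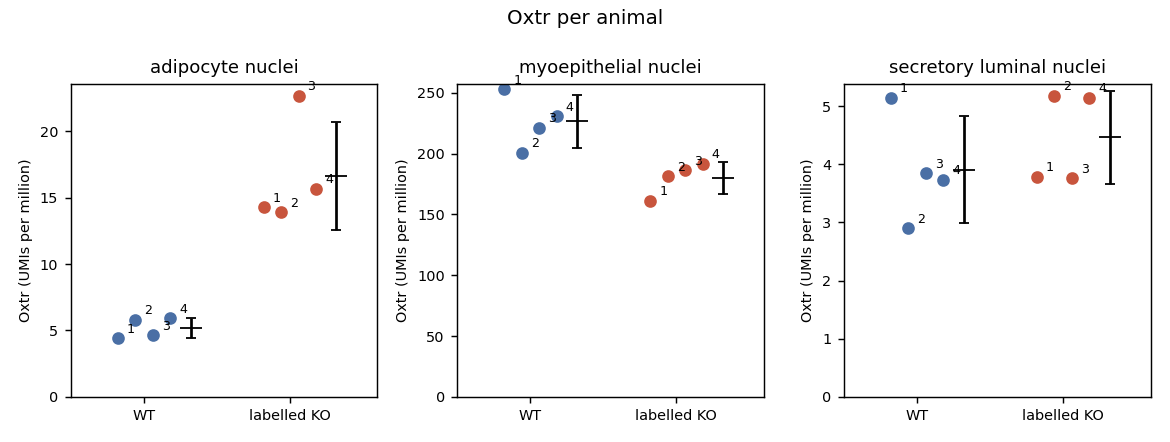
Oxtr in plain CPM (vertical axes, each starting at 0) in adipocyte, myoepithelial and secretory luminal nuclei of 4 WT animals and 4 animals labelled knockout; each point is an animal with its replicate number, and the bars give the mean and SD. In adipocyte nuclei the 4 animals labelled knockout lie between 13.9 and 22.7, above the 4 WT animals at 4.40 to 5.91, and in myoepithelial nuclei they lie below the WT animals.

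In adipocyte nuclei, Ofcc1 (ENSMUSG00000047094.10) fell from 101 ± 44.9 CPM in WT animals to 13.8 ± 4.46 CPM in the animals labelled knockout (SD, n = 4 each; log2 -2.86, SE 0.43, edgeR adjusted p = 0.0189), lower in 4 of 4. It was the only call among 3853 genes tested, 297 of which had an unadjusted p under 0.05. Its counts were low, 69 UMIs in WT animals and 13 in the animals labelled knockout, where each animal had 2 to 4. DESeq2 made 2 calls, Ofcc1 and a rise of Ugdh, the enzyme that makes UDP-glucuronate (log2 2.22, adjusted p = 0.00480; named after its values were seen). The lipid genes with the smallest p went both ways without passing. Lpin1 and Xdh lay higher, and others lay lower in the animals labelled knockout. Gpam, which starts glycerolipid synthesis, was at 745 ± 241 and 383 ± 46.4 CPM (log2 -0.96, adjusted p = 0.249), and Agpat2, the next acyltransferase, at 311 ± 114 and 155 ± 32.5 CPM (adjusted p = 0.294). Srebf1, the transcription factor of lipogenesis, had a log2 of -1.03 (adjusted p = 0.294), Acss2, which makes acetyl-CoA from acetate, -1.67 (0.412), and Ghr, the growth hormone receptor, -0.81 (0.223).

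The Ofcc1 call was lost without WT animal 1 (log2 -2.52, adjusted p = 0.160) and without animals 1, 3 or 4 labelled knockout (adjusted p = 0.0888, 0.110 and 0.0523). Ofcc1 was not among the genes tested when the highest Scrublet scores were removed, with all 10 hashtags or with the background rule. Without WT animal 4, 43 genes passed, 19 up and 24 down, and Ghr (log2 -0.97), Gpam (-1.14), Agpat2 (-1.14), Srebf1 (-1.16), Acss2 (-2.03), Me1 (-1.19) and Pparg, the master regulator of adipocytes (-0.82), were among those that fell, while Stat3 (1.13) was among those that rose. Me1 and Pparg were named after their values were seen. WT animal 4 lay at 1.18 on the first principal component of adipocyte sums without TMM scaling, and at 1.23 with it, on a scale where 0 is the mean of the other WT animals and 1 that of the animals labelled knockout. Its Pparg was 1497 CPM against 3462 to 3558 in the other WT animals.

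**Figure D2:**
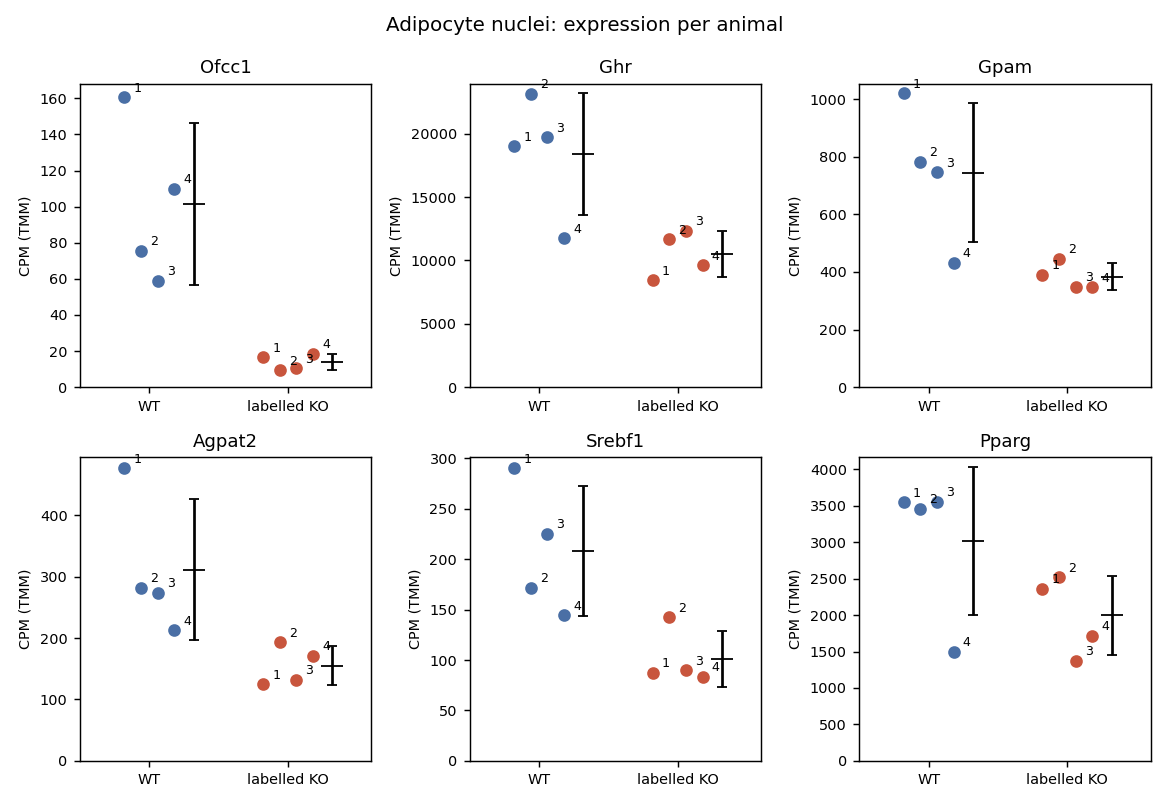
Expression of Ofcc1, Ghr, Gpam, Agpat2, Srebf1 and Pparg in adipocyte nuclei, in TMM-scaled CPM (vertical axes, each starting at 0), for 4 WT animals and 4 animals labelled knockout; points are animals with their replicate numbers and bars the mean and SD. Ofcc1 is at 9.48 to 18.5 in the animals labelled knockout against 59.0 to 161 in WT animals, and WT animal 4 lies among the animals labelled knockout for Ghr, Gpam and Pparg, the last plotted after its values were seen.

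Among the lists, camera called 3 of the 14 tested in adipocytes, and in each the members lay lower in the animals labelled knockout. Of 14 measured genes of adipocyte identity, 11 lay lower (adjusted p = 0.0115, and adjusted p = 0.168 with an estimated correlation). Ghr was the only one of them to pass when adjusted over the list alone (0.00568), and none passed over all genes. Of 15 genes of fatty acid synthesis, 11 lay lower (adjusted p = 0.0142, and 0.444 as the adjusted p with an estimated correlation), and Srebf1 alone passed adjusted over the list alone (0.0182). Of 13 genes of the respiratory chain, 12 lay lower (adjusted p = 0.0324, and 0.385 as the adjusted p with an estimated correlation), led by the citrate synthase gene Cs (log2 -0.68) and the complex I gene Ndufs1 (-0.55). Without WT animal 4 the respiratory chain was no longer called, and fatty acid synthesis had an adjusted p of 1.2e-06 (0.269 with an estimated correlation, where no list was called).

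Triglyceride synthesis went both ways, with 8 of 15 genes lower and no camera call (adjusted p = 0.305). Adjusted over the list alone, Gpam and Agpat2 fell and Lpin1, a phosphatidate phosphatase named after its values were seen, rose (log2 0.65, 0.0138 over the list alone, 0.327 over all genes). Lipolysis (17 genes, adjusted p = 0.542), with Adrb3 (the beta-3 adrenergic receptor) at a log2 of -0.39, and fatty acid uptake (8 genes, 0.286), with Fabp3 at 0.45, held no gene past either adjustment. Nor did fatty acid oxidation (12 genes, 0.270), where Ppargc1a, a coactivator of mitochondrial genes, had a log2 of 1.30, or insulin and glucose metabolism (15 genes, 0.305), where Slc2a4, the insulin-responsive glucose transporter, had -0.81. In the same order, the other of the 2 members with the smallest p were Pde4d (log2 0.53), Angptl4 (0.52), Ppara (0.81) and Tbc1d4 (-0.85). The extracellular matrix list (5 genes, adjusted p = 0.0705), led by Col4a1 at -0.85, was called without WT animal 4 (0.00328, and 0.269 with an estimated correlation). Involution (5 genes, 0.101), milk proteins (13 genes, 0.555), milk fat secretion (13 genes, 0.305), with Xdh at 0.54, oxytocin receptor signalling (9 genes, 0.305) and the clock (8 genes, 0.670) were not called. Cholesterol synthesis, inflammatory and immediate early genes had 4 measured members each, too few for the test, and no gene of theirs passed when adjusted over the list alone. No cell cycle gene was measured. Milk protein genes took 8.24 ± 0.490% of adipocyte UMIs in WT animals and 8.60 ± 0.736% in the animals labelled knockout (SD, n = 4 each, exact permutation p = 0.486), a measure of free RNA from secretory cells.

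In secretory luminal nuclei no gene passed in edgeR among 12860 tested, with 1096 at an unadjusted p under 0.05, and DESeq2 called 25 (13 up, 12 down). No difference in casein genes was detectable, but free RNA keeps this from deciding on the cells' own casein RNA. Csn2 (beta-casein) had a log2 fold change of -0.01 (SE 0.25), Csn1s1 0.00 (SE 0.24), Csn1s2a -0.07 (SE 0.29), Csn1s2b -0.19 (SE 0.33) and Csn3 -0.11 (SE 0.18). Wap, whey acidic protein and not a casein, had 0.09 (SE 0.19). These 6 were named after their values were seen. In WT animals, milk protein genes took 16.4% of secretory luminal UMIs on average. They also took 15.7% of vascular endothelial, 13.7% of macrophage and 8.24% of adipocyte UMIs there. Much of the casein RNA in secretory nuclei may thus be free RNA, which reaches all animals alike within the shared pool. The cells' own share of it was not tested. Lalba, the cofactor of lactose synthesis, was at 2740 ± 699 CPM in WT animals and 1636 ± 149 in the animals labelled knockout (log2 -0.74, edgeR adjusted p = 0.552), and Btn1a1 and Plin2, which coat milk fat globules and lipid droplets, had log2 values of -0.77 and -0.48 (adjusted p = 0.560 and 0.552). Without WT animal 4, 29 genes passed (12 up, 17 down), with Lalba (log2 -0.91) and Pnpla3, a lipase family member (-2.02; named after its values were seen), among those that fell. Adipor2, an adiponectin receptor (0.94), and Nr1d2, a clock repressor (0.93), were among those that rose.

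Camera called 6 of 18 lists in secretory luminal nuclei, each of them lost with an estimated correlation. Of 12 cell cycle genes 11 lay higher in the animals labelled knockout (adjusted p = 5.8e-07, and adjusted p = 0.209 with an estimated correlation). Adjusted over the list alone 5 rose, among them the spindle gene Tpx2 (log2 1.71) and the replication gene Mcm6 (0.96), none over all genes, and Tpx2 was at 0.816 ± 0.439 and 2.72 ± 2.09 CPM. Clock genes (11 of 16 higher, adjusted p = 0.00376, and adjusted p = 0.421 with an estimated correlation) were led by Nr1d2 (log2 0.73, 0.0380 over the list alone) and Tef (0.63). All 15 genes of fatty acid oxidation lay higher (adjusted p = 0.00376, and adjusted p = 0.421 with an estimated correlation), with Cpt1a, which admits fatty acids to mitochondria, at 1.04 and Acadl at 0.93. Of 18 genes of cholesterol synthesis 14 lay lower (adjusted p = 0.00500, and adjusted p = 0.648 with an estimated correlation), with Msmo1 at -0.88 and Fdps at -0.41.

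The adipocyte identity list lay higher in secretory nuclei (10 of 11 genes, adjusted p = 0.0108, and adjusted p = 0.209 with an estimated correlation), led by Adipor2 (log2 0.66), a gene that secretory cells also express. Of 6 inflammatory genes 5 lay higher (adjusted p = 0.0241, and adjusted p = 0.209 with an estimated correlation), led by Lcn2, an acute phase protein (0.70), and Nfkbia (0.38). The other 12 lists had adjusted p from 0.132 (milk fat secretion, 12 of 15 genes lower) to 0.972 (oxytocin receptor signalling, median log2 -0.03 and mean 0.03). They were milk proteins (0.224), fatty acid synthesis (0.971), triglyceride synthesis (0.971), fatty acid uptake (0.971), lipolysis (0.971), the respiratory chain (0.340), insulin and glucose metabolism (0.971), extracellular matrix (0.216), immediate early genes (0.207) and involution (0.340). Pkm, a glycolytic enzyme, was the only gene of these to pass over its list alone (log2 -0.69, 0.0158). Secretory nuclei fell into 3 clusters, and different ones held most of them by genotype, though no share passed a test. The one led by Plpp4 and Elovl5 held 54.4 ± 29.0% of them in WT animals (13.1% in WT animal 4) and 37.5 ± 5.32% in the animals labelled knockout, where the one led by Ucp3 and Slc28a3 held most (55.0 ± 5.59%; SD, n = 4 each). The exact permutation p was 0.314 and 0.371 for these clusters. The third cluster, led by Gm42047 and Gm49980 with Slc28a3, Gldc and Spc25 among its 10 leading genes, held 5.23 ± 0.983% and 7.51 ± 0.976% (SD, n = 4 each, exact permutation p = 0.0286, adjusted 0.0857). Plpp4 itself differs between the genotypes in other cell types, and Spc25 in secretory nuclei when WT animal 4 is left out, so these shares are no measure of cell numbers. WT animal 4 lay at 1.18 on the first component of secretory sums (1.14 with TMM scaling), beyond the mean of the animals labelled knockout.

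Outside these types, 3 changes passed in 6 cell types. Got1 (ENSMUSG00000025190.14), cytosolic aspartate aminotransferase, rose in myoepithelial nuclei from 123 ± 10.8 to 373 ± 49.5 CPM (SD, n = 4 each; log2 1.58, SE 0.15, edgeR adjusted p = 9.8e-06), higher in 4 of 4. In secretory luminal nuclei Got1 stood at 360 ± 39.8 and 714 ± 102 CPM (log2 0.96, edgeR adjusted p = 0.436; DESeq2 called it, adjusted p = 2.7e-07). Got1 lay higher in the animals labelled knockout in all 8 cell types, by a log2 CPM ratio of 0.72 to 1.601 (luminal progenitors 1.39, exact permutation p = 0.0286). In myoepithelial nuclei it was at 0.382 to 0.749 (median 0.542) of the level that free secretory RNA would bring by the scale of the milk proteins, so the rise is not shown to be of these cells. Plpp4 (ENSMUSG00000070366.6), a lipid phosphatase, fell in vascular endothelial nuclei from 285 ± 125 to 39.5 ± 34.4 CPM (SD, n = 4 each; log2 -2.74, SE 0.47, adjusted p = 0.0432). In macrophage nuclei it fell from 267 ± 115 (SD, n = 3) to 48.1 ± 12.5 CPM (SD, n = 4; log2 -2.38, SE 0.39, edgeR adjusted p = 0.0232); WT animal 1 had fewer than 10 macrophages. In secretory nuclei, where Plpp4 marks a cluster, it stood at 313 ± 166 and 115 ± 66.3 CPM (exact permutation p = 0.0571 with n = 4 each). The log2 CPM ratio of Plpp4 was -1.83 in fibroblasts (exact permutation p = 0.0286), -0.91 in the cluster led by Klra2, -0.89 in myoepithelial nuclei, -0.26 in adipocytes and 0.46 in luminal progenitors. On the scale of the milk proteins Plpp4 was at 0.245 to 1.30 (median 0.62) of the free-RNA level in endothelial nuclei. In macrophage nuclei it was at 0.267 to 1.24 (median 0.88), so neither fall is shown to be of these cells.

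Fibroblasts, luminal progenitors and the cluster led by Klra2 gave 0 calls in edgeR and 0 in DESeq2, with 356, 173 and 274 genes at an unadjusted p under 0.05 in edgeR. The Got1 call was lost when the highest Scrublet scores were removed (log2 0.94, adjusted p = 0.443) and with centred log ratios within barcodes (1.49, 0.117), and the ratio rule gave 0.73 (0.991). The macrophage call of Plpp4 was lost without WT animals 2 or 3 (adjusted p = 0.221 and 0.144) and without animals 1 or 3 labelled knockout (0.0555 and 0.120), and the endothelial one without WT animals 2 or 3 (0.235 and 0.343) and without animals 1, 3 or 4 labelled knockout (0.420, 0.101 and 0.0906). The background rule ended both Plpp4 calls (macrophage 0.1004, endothelial 0.0829). The endothelial one was also lost without the highest Scrublet scores (log2 -2.41, 0.606, with only 2 WT animals left), with all 10 hashtags (0.654) and with centred log ratios within barcodes (0.819). In macrophages Plpp4 was not tested with the last of these or with all 10 hashtags. Without WT animal 4, 22 genes passed over the 6 types.

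**Figure D3:**
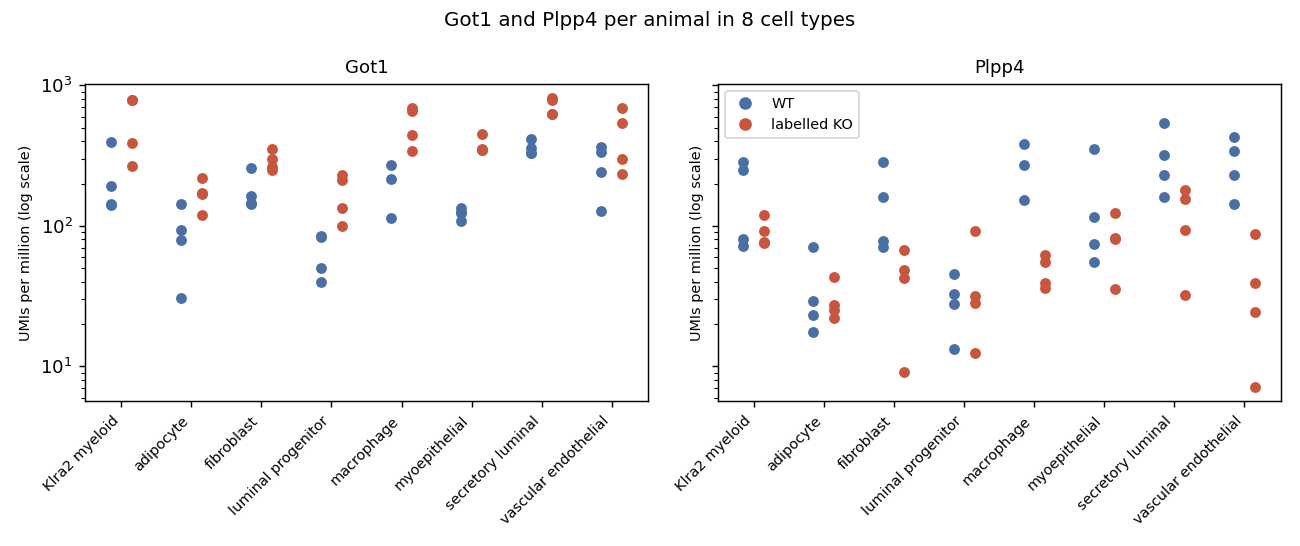
Got1 and Plpp4 in plain CPM (log axes) in the summed nuclei of 8 cell types; each point is 1 animal, WT or labelled knockout. In myoepithelial nuclei the 4 animals labelled knockout lie at 345 to 447 for Got1 against 108 to 134 in WT animals, and secretory luminal nuclei have the highest Got1 mean.

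Shares of nuclei did not differ past the adjusted threshold for any of the 12 cell types compared, the smallest adjusted p being 0.386. Adipocytes were 2.41 ± 0.303% of assigned nuclei in WT animals and 3.37 ± 0.686% in the animals labelled knockout (SD, n = 4 each, exact permutation p = 0.0857). Secretory luminal nuclei were 76.8 ± 6.15% and 71.8 ± 3.91% (SD, n = 4 each, exact permutation p = 0.257), fibroblasts 4.63 ± 1.37% and 6.08 ± 0.934% (exact permutation p = 0.171), and myoepithelial nuclei 7.15 ± 2.45% and 7.08 ± 1.11% (exact permutation p = 1). Hashtag capture limits these shares: no hashtag was called in 10.6% of secretory luminal, 20.2% of adipocyte, 51.6% of myoepithelial, 60.8% of fibroblast and 69.1% of vascular endothelial nuclei, which have lower median UMIs (1701 in endothelial against 5080 in secretory nuclei). Shares are therefore of nuclei with a called animal, not of tissue.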

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

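The tests of myoepithelial RNA as the only source of Oxtr, of exchanged genotype names, and of secretory RNA as the only source of the Plpp4 and Got1 changes were chosen only after the results were seen, and the criteria of the first and the last were changed after their outcomes were known.

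Oxtr was higher, not lower, in adipocyte nuclei of the animals labelled knockout, and its change there differed from that in myoepithelial nuclei by 1.99 on the log2 scale (1.66 against -0.33, exact permutation p = 0.0286, adjusted 0.114 over 8 comparisons). Fibroblasts (5 and 21 UMIs), macrophages (3 and 9) and the cluster led by Klra2 (6 and 18) differed the same way without passing, much of it from single animals. RNA of myoepithelial cells, as a part or the only source, stays open: their other markers allow 7.79 Oxtr UMIs in the animals labelled knockout where 18 were counted (lower Poisson bound 10.7), but in 3 of 4 animals they reach the animal's own lower bound, and the ratio of 10 markers was 1.53 with an interval of 0.479 to 4.87. Genotype names exchanged on all hashtags cannot be told apart from names as given: 4 of 4 WT animals lay below every animal labelled knockout, and no other gene marks the deletion. A response of the Oxtr gene to the genotype, with tags outside the deleted part, is open and untested.

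Plpp4 fell in macrophage and vascular endothelial nuclei and Got1 rose in myoepithelial nuclei, while secretory luminal nuclei differed the same way by less (log2 of the CPM ratio for Plpp4 -1.44 against -2.47 in macrophages and -2.85 in endothelial nuclei, and for Got1 0.99 against 1.601 in myoepithelial nuclei). RNA free in the shared pool reaches all animals alike, so free secretory RNA as the only source would have to stick to nuclei before pooling and leave each gene's ratio to secretory nuclei, over that of the milk protein genes, alike in both genotypes. For endothelial Plpp4 this is argued against only as far as the milk protein scale holds. Its log2 difference was -1.71 (95% interval widened for 3 tests -2.57 to -0.86, and -1.92 to -1.57 leaving out 1 animal). The exact permutation p was 0.0286, and 0.0857 when adjusted over the 3 tests. Against adipocyte and luminal progenitor nuclei the difference was -3.08 and -3.39 (exact permutation p = 0.0571 and 0.0286, intervals excluding 0), though on 31 UMIs in the animals labelled knockout. Endothelial Plpp4 was at 0.781 to 1.30 of the free-RNA level in WT animals and 0.245 to 0.458 in the animals labelled knockout. Values under that level put the scale in doubt, so a change of endothelial cells is not shown. Free secretory RNA as the only source stays open for macrophage Plpp4 (-0.71, interval -2.39 to 0.97) and myoepithelial Got1 (0.52, interval -0.07 to 1.11). A change within these cell types by genotype is open and untested.

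The adipocyte identity list differed in its effect between adipocyte and secretory luminal nuclei by -0.40 on the log2 scale (11 genes, -0.19 against 0.21, exact permutation p = 0.0286, adjusted 0.114). A sample stood far from the other 3 of its genotype in 8 of 84 groups of 4, where chance gives about 1 in 20. Dendritic nuclei were 0.0722% in WT animal 4 and 0.642% in animal 3 labelled knockout, and pericytes 0.0703% in animal 4 labelled knockout. These shares rest on very few nuclei. The dendritic cluster held 21 in all and the pericyte cluster 145, of which 52.4% and 78.6% had no called hashtag. The rate of 1 in 20 does not hold for counts this low. Secretory luminal nuclei were 77.7% in animal 1 labelled knockout. Oxtr in vascular endothelial nuclei was 63.6 CPM in WT animal 1 (5 UMIs in 13 nuclei), and Got1 in myoepithelial nuclei 447 CPM in animal 4 labelled knockout. Milk protein genes took 17.9% of secretory UMIs in WT animal 1 and 11.999% in animal 3 labelled knockout. Of the nuclei with the hashtag Unknown_sample2, which the labels put in no group, 240 lay in the cluster led by Nrg3 and Kcnip4.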

How the results depend on the processing

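The settings with all 10 hashtags, centred log ratios within barcodes, the background rule, the removal by Scrublet score and, for the gene lists, the block, the minimum of 1000 UMIs and an estimated correlation without WT animal 4 were chosen only after the data were seen.

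In adipocytes, where 1 gene was called, DESeq2 called 2 and no filter 81. Removal by Scrublet score, all 10 hashtags and the background rule each called 0 in edgeR, where Ofcc1 was no longer among the genes tested. Leaving out 1 animal gave 0 to 43. In secretory luminal nuclei, where edgeR called 0, DESeq2 called 25, and leaving out 1 animal gave 0 to 29. In the 6 other types, with 3 calls, no filter gave 160, Scrublet removal 1, all 10 hashtags 1, the background rule 1 and centred log ratios within barcodes 0. The ratio rule gave 0 and left only myoepithelial nuclei to test, and leaving out 1 animal gave 1 to 22. The ratio rule left too few adipocytes for a fit.

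Of 3 lists called in adipocytes, an estimated correlation and fry each left 0, all 10 hashtags 1, and leaving out 1 animal 2 to 5. Of 6 in secretory luminal nuclei, an estimated correlation and fry each left 0, and leaving out 1 animal 2 to 8. An estimated correlation without WT animal 4 left 0 in both.

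The adipocyte Oxtr difference was 11.6 CPM with all 10 hashtags (exact permutation p = 0.4) and 12.8 CPM with the background rule (exact permutation p = 0.0857). Without the highest Scrublet scores it fell from 11.4 to 7.19 CPM. The myoepithelial difference reversed to 70.5 CPM with the ratio rule, and the difference in median depth to 173 UMIs. Except where fewer genes, animals or cell types were left, the cause was not tested.

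The replicate number as a block gave 8 genes in adipocytes, 0 in secretory luminal nuclei and 24 in the 6 other types, and 3 and 7 lists. Ghr was among the 8 in adipocytes (log2 -0.78, edgeR adjusted p = 0.0205). Animals with the same number correlated at 0.03, 0.11, 0.05 and 0.26 in adipocytes and 0.23, -0.02, 0.24 and 0.14 in secretory luminal nuclei. Animals with unlike numbers correlated at -0.32 to 0.20 and at -0.33 to 0.38. Not every animal correlated best with its own number, so pairing by number is neither shown nor excluded. Of the values for named genes under alternatives, 1276 kept their direction and side of the threshold, 21 became weaker, 18 stronger and 7 moved. The first count says little, since nearly all named genes were uncalled in the main fit and count as kept while uncalled. Only a called gene could become weaker, so all 21 are lost calls of Got1, Ofcc1 or Plpp4. Depth limits the small types most: macrophages had 76662 to 176662 summed UMIs per animal, vascular endothelial nuclei 76539 to 245550, luminal progenitors 74918 to 247419 and the cluster led by Klra2 66535 to 309106, against 169108 to 360073 in adipocytes.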

Other observations

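The test of a wrong genotype name and all counts over other splits of the animals were chosen only after the results were seen.

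Without WT animal 4, secretory luminal nuclei of the animals labelled knockout had higher Spc25, a kinetochore gene (log2 1.27, edgeR adjusted p = 0.0173), Bhlhe40, a clock regulator (1.599), and Wee1, a cell cycle kinase (1.12). Kcnj2, a potassium channel (-2.15), and Smad3, a mediator of TGF-beta (-0.94), were lower. In adipocytes Igf1 (-1.97) was lower and Vdr, the vitamin D receptor (1.98), higher. In fibroblasts 9 genes passed, among them Got1 (0.92), Plpp4 (-2.02) and Btn1a1 (-0.95), and Spp1 was higher in luminal progenitors (2.40) and in the cluster led by Klra2 (2.36). Btn1a1 and Spp1 are among the 219 free-RNA genes, Spp1 as a member of the milk protein list. G0s2 (-1.49) and Fhip1b (-1.04), 2 more of the 9 in fibroblasts, are also among them. Over all 8 animals Btn1a1 differed in the same direction in secretory luminal nuclei (-0.77), as did Spp1 (0.79). Secretory RNA is thus not excluded as their source. These genes were named after their values were seen.

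WT animal 4 stood with the animals labelled knockout, at a position of 1.18 in adipocyte and in secretory luminal nuclei without TMM scaling (1.23 and 1.14 with it), on a scale where 0 is the mean of the other WT animals. Depth of the summed libraries is argued against, since the lower of both positions was 1.16 after thinning them to the same total. Thinning sums cannot decide on depth per nucleus. Its median was 4713 UMIs in this animal, 5048 to 5657 in the other WT animals and 4296.5 to 5184 in the animals labelled knockout. In adipocyte nuclei it was 4113, against 4110.5 in WT animal 3. Without the 219 free-RNA genes the lower was 1.17, which cannot decide on free RNA of secretory cells. Genes such as Got1 and Plpp4 are outside that list, and in secretory luminal nuclei this RNA is the cells' own. A wrong genotype name on its hashtag may explain it: at 91.5% of the genes called without it (37 of 42 in adipocytes, 28 of 29 in secretory luminal nuclei) it lay nearer the knockout mean, but these genes were chosen for the pattern, and 3 stayed at the WT mean, Ofcc1 (-0.11), Rab30 (0.16) and Got1 in secretory nuclei (0.16). The share leaves out Mup10, called without this animal but not among the genes tested over all 8 (Rab30 and Mup10 were named after their values were seen). It also leaves out the other cell types. Got1 in myoepithelial nuclei was at 126 CPM in this animal, among the other WT animals (108 to 134) and below the animals labelled knockout (345 to 447). Plpp4 in this animal lay between the groups, at 143 CPM in endothelial and 152 CPM in macrophage nuclei. Oxtr in adipocytes, 5.91 CPM in this animal, was tried first and decided nothing, so the name stays open, as does litter size: the labels list the litter of 3 in place 4 of 8, which would be this animal if listed by genotype and animal 2 labelled knockout if listed by hashtag, and no source used here says which.

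Over 35 splits of the 8 animals, chance could not be excluded for the counts of genes in adipocytes and in the 6 other types or for the counts of lists. In adipocytes 4 splits gave at least the 1 real gene, the highest other being 157, with WT animals 1 to 3 and animal 2 labelled knockout against the rest. On the first component of adipocyte sums with TMM scaling, animal 2 labelled knockout lay at -3.26. The other animals labelled knockout lay at 5.32 to 12.6 and WT animals 1 to 3 at -13.2 to -8.34. What sets these samples apart was not tested. In secretory luminal nuclei edgeR called 0 genes in the real split, with 1096 at an unadjusted p under 0.05 and 25 calls in DESeq2, and 0 in every one of the 35. A real count of 0 is reached by all 35 by construction, so this decides nothing. At an unadjusted p under 0.05, 4 other splits gave more secretory genes than the real 1096 (highest 2024), each setting WT animals 1 to 3 and 1 animal labelled knockout against the rest, and 3 gave more adipocyte genes than the real 297 (highest 592). In the 6 other types 5 splits gave at least the 3 real genes (highest other 18). For lists, 3 splits gave at least the 3 real ones in adipocytes (highest other 6), and 5 splits at least the 6 real ones in secretory luminal nuclei (highest other 9).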
